A study of Mus musculus with 6 samples.

How the data were processed

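The series holds 6 samples of exosomal RNA from RAW 264.7 cells, 3 control and 3 LPS, grouped by the treatment named in the labels. Per the labels' protocols, supernatant of cells given 2 µg/mL LPS was collected after 72 h, concentrated at 1500 × g for 20 min and passed over size-exclusion columns, and fractions 7 to 9 of 0.5 mL were pooled as exosomes. The label protocol names 0.5 µg of RNA and a Cy3 low-input amplification kit for cRNA, which is unusual for a miRNA array. Each array's scanner output was deposited as linear intensity values, background-subtracted per the file headers by Agilent Feature Extraction 10.7.1.1. The submitters' processing notes name version 9.1 instead. The authors also deposited a value table on a log2 scale, with column medians of 2.73 to 2.74; how it was normalized is not given in the sources used here. Its values correlated with the log2 processed signal of detected miRNAs at r = 0.903 to 0.972 across miRNAs, and it was used as an alternative.

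Processed signal was averaged over the spots of each probe, leaving out control spots and outlier spots. A miRNA was represented by its brightest probe over the 6 arrays and called detected by the detection flag in the files. Each array was divided by its 75th percentile over the miRNAs detected on all arrays, values were then floored at 13.0 (3.70 on the log2 scale, the median over arrays of the lowest scaled value of detected miRNAs), and log2 was taken. A miRNA was tested when it was detected on 3 of 3 arrays of at least 1 group, which gave 412. LPS minus control was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes of at least 2-fold were also counted. Lists with 3 or more tested members, 13 of the 15 fixed, were tested with camera at a preset correlation of 0.01 against the other tested miRNAs, with an estimated correlation beside it, and with fry, also over the members detected on all 6 arrays. Single measures per array were compared by a two-sided exact permutation test. A miRNA detected in one group only is given as a bound, the mean of the bright group over the higher of the dim group's own signal and the array's lowest signal well above background; a named miRNA that was detected in a group but well above background on none of its arrays is given the same way. Directions of miRNAs with no bound above 1 are not read.

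The groups, the tests, the scaling, the lists and the alternatives to try were fixed before the data were examined. So was the rule for named miRNAs: the 10 highest and 10 lowest log2 changes among called miRNAs whose groups do not overlap, 8 fixed macrophage miRNAs, up to 4 members of each list, the 5 brightest miRNAs, and the 5 largest bounds in each direction. The lists cover LPS-induced, LPS-repressed, myeloid, let-7, miR-17~92, miR-232724, miR-29 and miR-30, miR-15/16, and p53 and hypoxia miRNAs, serum and erythroid, epithelial, mesenchymal and muscle, lymphocyte and neural markers, and miRNAs numbered 1000 or above. Other members of a list are named in some sentences and were chosen after their values were seen. The alternatives were the percentile over all miRNAs, no scaling, quantile normalization, median centring, normexp with an offset of 50, the gene total signal, the mean over probes, the value table, other filters, detection calls and floors, a trended robust variance, array weights, the replicate number or the slide row as a block, and leaving out each replicate. Scaling to 4 spiked-in RNAs, a higher floor and a comparison within the first slide row were added after the data were seen. All 74 named miRNAs were matched to the mouse gene table of assembly GRCm38.p6, used for names and neighbours only; coordinates are the mm9 probe positions in the files, given for 41 miRNAs with 1 position.

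The fit was checked on simulated data over 412 miRNAs: it recovered 90% of changes of 0.5 on the log2 scale, 98% of changes of 1, and 100% of changes of 2 and of 3, and called 5 of 212 unchanged miRNAs. In 260 list tests on unchanged simulated data 2 were called. The simulated miRNAs were drawn independently, so this does not cover lists whose members vary together. Values were drawn on the scaled log2 scale, so the check does not cover array brightness, scaling, the floor or the detection filter. In the real data the estimated correlation within a list reached 0.51, for miR-232724. No per-sample columns were left unused. No replicates of a group held identical values over the 198 miRNAs detected on all arrays. The first principal component held 98.5% of the variance and separated the groups, with r from 0.996 to 0.9996 within groups and 0.771 to 0.781 between them. The gene total signal in the files was used only as an alternative: it equals the sum of its probe totals only where every probe exceeds 3 errors, so miR-155-5p had 462 against a probe sum of 12.3 on control 1. A miRNA counts as detected in the files when any probe exceeds 3 errors, which held for 1881 of 1881 miRNAs on each array.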

Results

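Exosomes are small vesicles that cells release, and they carry miRNAs. The series compared the exosomal miRNAs of RAW 264.7 cells, a mouse macrophage line, with and without lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages through TLR4. Exosomes from 3 control and 3 LPS samples were measured on 6 one-colour Agilent mouse miRNA arrays. LPS was given at 2 µg/mL and the supernatant was taken after 72 h. No incubation time was recorded for the control samples, so a difference in culture time could not be told apart from LPS. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The arrays hold 1881 mouse miRNAs in 4415 probes, and 1417 of the miRNAs were detected on no array. The number of arrays limits the precision of each value.

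The LPS arrays detected 1.96 times as many miRNAs as the control arrays. They were also brighter before scaling, which lets more miRNAs pass detection whatever its source. The control arrays detected 219 ± 8.14 miRNAs (SD, n = 3) and the LPS arrays 428 ± 17.1 (SD, n = 3), a difference of 209 with p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 samples allow. Before scaling, the 75th percentile of the miRNAs detected on all 6 arrays was 477 ± 41.0 (SD, n = 3) in control and 2229 ± 180 (SD, n = 3) in LPS, a 4.67-fold difference (exact permutation p = 0.1). The geometric mean of the 4 RNAs that the files mark as spike-ins was 2531 ± 88.1 in control and 2227 ± 209 in LPS (SD, n = 3), a ratio of 0.880. Their log2 differences were −0.31 for dmr_285, −0.45 for dmr_31a, 0.01 for dmr_3 and −0.01 for dmr_6. miRNAs numbered 1000 or above, which were registered later and often at low abundance, supplied 67.9% ± 0.302 of the detected signal in control and 47.3% ± 1.0998 in LPS (SD, n = 3; exact permutation p = 0.1). The 5 brightest miRNAs took 36.2% ± 0.529 and 36.5% ± 0.677 (SD, n = 3; exact permutation p = 0.5).

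**Figure D1:**
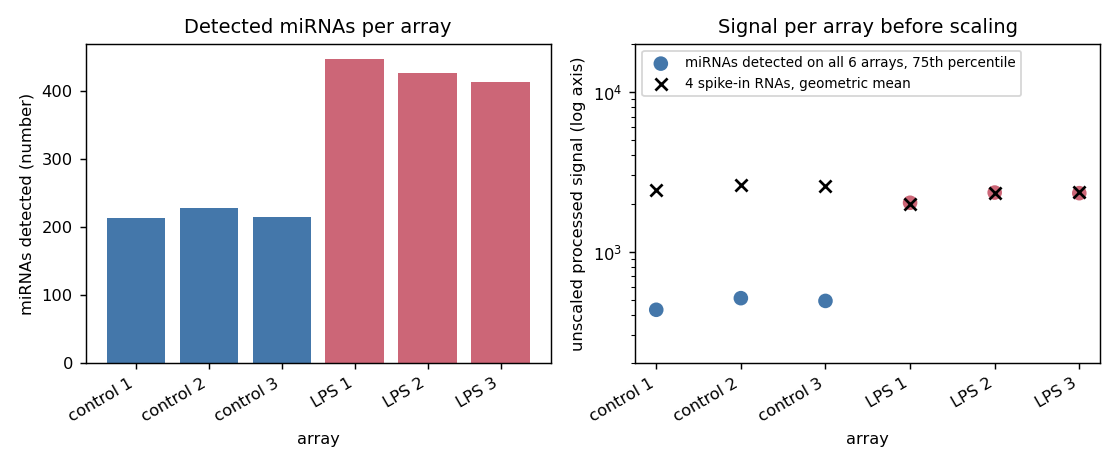
Left, number of miRNAs detected on each array; right, the 75th percentile of the unscaled processed signal of miRNAs detected on all 6 arrays (circles) and the geometric mean of the 4 spiked-in RNAs (crosses), on a log axis. Control arrays lie between 213 and 228 detected miRNAs and LPS arrays between 412 and 446, while the spiked-in RNAs stay between 1989 and 2596.

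After scaling each array to the miRNAs shared by all 6 arrays, exosomal miR-155-5p, miR-709 and miR-210-3p were among the miRNAs with the largest rises. miR-155-5p, a miRNA induced by Toll-like receptor signalling, rose by 4.18 on the log2 scale (SE 0.07, 18.2-fold, adjusted p = 1.72e-08 in limma with Benjamini-Hochberg adjustment). miR-210-3p, the hypoxia-responsive miRNA, was detected on 2 of the 3 control arrays but well above background on none, and was at least 12.6-fold higher in LPS (adjusted p = 4.71e-09). miR-709 rose by 3.83 (SE 0.07), miR-146b-5p by 3.05 (SE 0.08) and miR-221-3p by 3.003 (SE 0.05), each in 3 of 3 samples against every control. At the other end miR-6946-5p fell by 4.23 (SE 0.04) and miR-300-5p fell by 4.12 (SE 0.04), both with adjusted p = 4.71e-09. The probes of both contain TCTC, a repeat-like stretch taken up under the other observations, and may bind RNA other than the named miRNA. Of 412 miRNAs tested, 270 were called higher and 110 lower in LPS, and 32 did not pass; with at least a 2-fold change the counts were 182 and 70. Among the 198 miRNAs detected on all 6 arrays, 115 were higher, 76 lower and 7 not past the test. Of the calls, 145 higher and 19 lower concerned miRNAs detected in LPS only. Of the 145, 34 had a bound above 1, and the direction of the rest is not readable. The 2-fold higher count of 182 includes such miRNAs, whose change is measured from the floor, and only 10 of them had a bound of at least 2-fold. A fit of the 198 miRNAs alone gave 81 higher by at least 2-fold. Another 39 miRNAs detected in both groups were well above background on no control array; 21 of the 22 called higher among them had a bound above 1, and the direction of the 14 called lower is not readable. The median log2 change over the 198 miRNAs was 0.77; it was 3.18 when arrays were scaled to the spiked-in RNAs, an alternative chosen after the data were seen, 2.99 without scaling, 1.96 with the percentile over all miRNAs, 0.45 with median centring, 0.35 with quantile normalization and 0.11 with normexp. Over all 412 tested it was 0.85, and −0.58 with normexp. Other settings tested other miRNAs and set the floor anew from the arrays kept: the median over all tested was 0 within slide row 1 (449 tested). It was within rounding of 0 without LPS replicate 1 (416 tested) or without LPS replicate 3 (424 tested). Over the 198 miRNAs the median stayed at 0.80 within row 1, 0.78 without LPS replicate 1 and 0.77 without LPS replicate 3.

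Calls in both directions depended on the processing. Higher calls made up 71.1% of all calls here, against 85.1% with the 75th percentile over all miRNAs, 90.3% without scaling, 90.7% with spiked-in RNAs and 28.5% with normexp background correction. With spike-in scaling 369 were higher and 38 lower; all 270 higher calls held, while of the 110 lower calls 38 held, 67 turned higher and 5 lost their call. With normexp the 110 lower calls held, while of the 270 higher calls 112 held and 143 turned lower; with the gene total signal of the files 226 higher and 70 lower calls held, 20 turned lower and 22 turned higher. All arrays shared 1 slide and 1 scan, with LPS 1 and the controls in its first row. The effective feature size fraction in the files differed by group: the 3 control arrays had the default of 0.6 and the LPS arrays measured values of 0.812 to 0.829. With the row as a block 267 were higher and 102 lower; within row 1 LPS 1 against the 3 controls gave 182 and 76, with the spread supplied by the controls alone. The gene total signal reversed several named miRNAs, among them miR-155-5p at −1.04, miR-146b-5p at −1.79, miR-128-3p at −0.79, miR-34c-5p at −1.68 and miR-300-5p at 0.14. Without LPS replicate 1, where the floor was set anew from the arrays kept, the 2-fold higher count was 116. Among miRNAs detected on every array, 116 were then called higher, against 115 in the main fit.

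**Figure D2:**
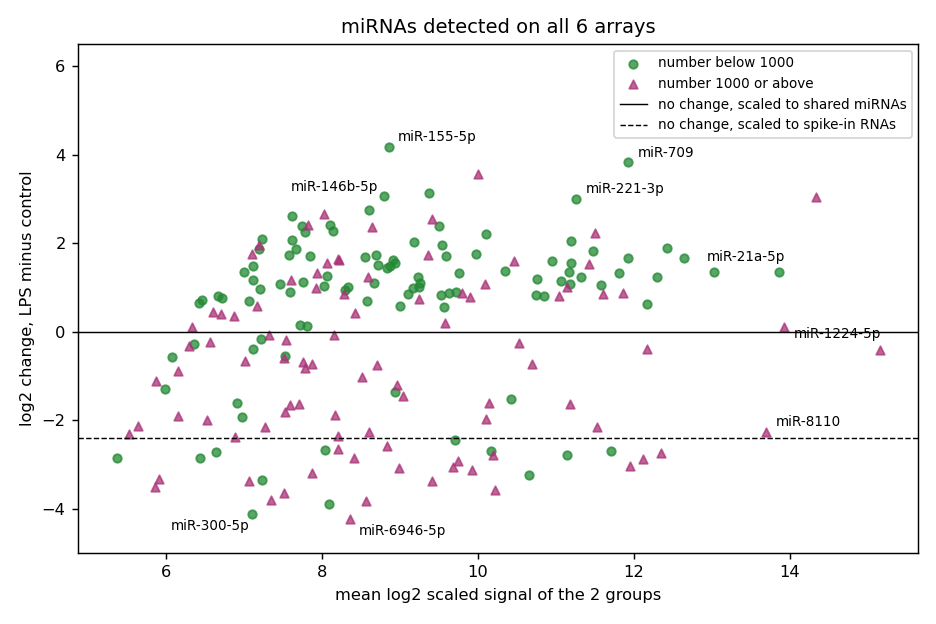
Log2 change (LPS minus control) against mean log2 scaled signal for the 198 miRNAs detected on all 6 arrays, 16 of them well above background on no control array; circles are miRNAs numbered below 1000 and triangles those numbered 1000 or above. The solid line marks no change with the scaling used here, and the dashed line no change with spike-in scaling, which lies 2.41 lower, so points between the lines change direction.

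Members of the list of miRNAs known to rise in LPS-stimulated macrophages were higher in LPS. All 16 of its tested members passed as higher in LPS (16 adjusted over the list alone), 9 of them detected on all 6 arrays with changes from 0.85 to 4.18. miR-146a-5p, a brake on Toll-like receptor signalling, rose by 1.34 (SE 0.06, 2.54-fold, adjusted p = 1.26e-06). miR-21a-5p rose by 1.36 (SE 0.05), miR-222-3p by 2.74 and miR-132-3p by 0.85 (SE 0.04). A further 6 members were detected in LPS only, of which miR-125a-5p and let-7e-5p had a bound above 1, at least 1.27-fold and 1.71-fold; the others, miR-212-3p, miR-9-3p, miR-21a-3p and miR-99b-5p, had no bound above 1. The list stood above the other tested miRNAs by 1.51 in camera (adjusted p = 0.0161; adjusted p = 0.478 with an estimated correlation), by 1.45 with the slide row as a block and by 1.46 within row 1, which holds 1 LPS array. No list was called higher without scaling, with spike-in scaling, with quantile normalization, with the percentile over all miRNAs, with the gene total signal or with the value table.

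In the mm9 coordinates of the files, the probe of miR-155-5p lies on chromosome 16 at 84714394 to 84714410, and the mouse gene table places this miRNA in Mir155hg. The probe of miR-146a-5p lies on chromosome 11 at 43187908 to 43187925, and that of miR-21a-5p on chromosome 11 at 86397588 to 86397607, within Vmp1. miR-210-3p maps to chromosome 7 at 148407355 to 148407369, and miR-221-3p to chromosome X at 18723483 to 18723501, next to Mir222. miR-300-5p lies on chromosome 12 at 110962531 to 110962549 in a large miRNA cluster with Mir134 and Mir494. miR-30c-2-3p lies on chromosome 1 at 23298597 to 23298614.

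**Figure D3:**
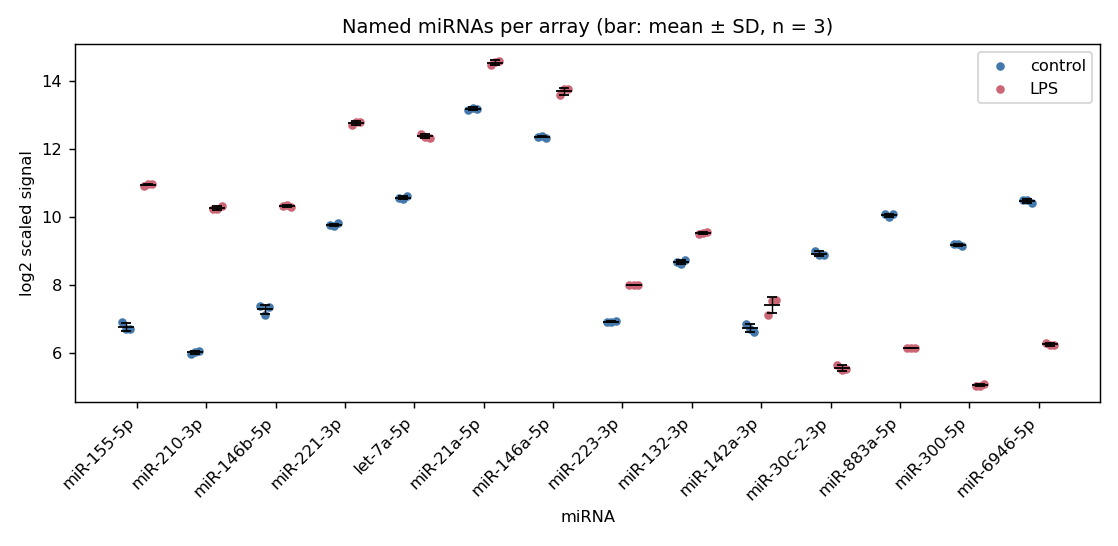
Log2 scaled signal of 14 miRNAs on each array, with control and LPS points coloured apart and bars giving mean ± SD (n = 3); the control points of miR-210-3p are not well above background. miR-155-5p goes from 6.77 to 10.95 and miR-6946-5p from 10.47 to 6.24.

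miRNAs reported to fall in stimulated macrophages were higher in these exosomes. All 10 tested members of that list passed as higher (10 adjusted over the list alone), from 0.63 for miR-92a-3p to 2.06 for miR-125b-5p, apart from miR-103-3p, which was well above background on no control array and at least 4.98-fold higher. miR-125b-5p, which targets Tnf mRNA, rose by 2.06 (SE 0.07), and the neutrophil and monocyte miRNA miR-223-3p was at 1.08 (SE 0.03), a call that ended with normexp (0.084). The list stood 0.97 above the other tested miRNAs (camera adjusted p = 0.0441; adjusted p = 0.478 with an estimated correlation). The difference was 0.90 with the slide row as a block, which ended the call, and 1.24 within row 1. The replicate block ended the call too. The 10 members were detected on all 6 arrays, where 115 of 198 miRNAs were called higher.

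Members of the let-7 family and of the list of miR-17~92 and its paralogue clusters that were detected on all 6 arrays were higher in LPS, 8 of 8 and 9 of 9. All 10 tested let-7 family members passed as higher (10 adjusted over the list alone), among them let-7g-5p at 2.39 (SE 0.04), let-7d-5p at 2.03 (SE 0.06) and let-7a-5p at 1.81 (SE 0.05, 3.51-fold), with a camera adjusted p of 0.0441 (adjusted p = 0.478 with an estimated correlation). Its members let-7e-5p and let-7k were detected in LPS only, the latter with no bound above 1. The list's difference from the other tested miRNAs was 1.07, and the call ended with the slide row as a block (1.07), within row 1 (1.32) and with the replicate block. All 13 tested members of the miR-17~92 list passed as higher (13 adjusted over the list alone), with miR-106b-5p, of the paralogue cluster within Mcm7, at 1.74 and miR-18a-5p, of the growth-promoting miR-17~92 cluster, at 1.68. Of the 13, 4 were detected in LPS only, of which miR-17-5p alone had a bound above 1, at least 2.21-fold. The list stood 0.80 above the other tested miRNAs (camera adjusted p = 0.0497; adjusted p = 0.585 with an estimated correlation), and 0.78 within row 1. The call was lost with median centring, without control replicate 2 and without LPS replicate 2. It was also lost with the replicate block and with the slide row as a block (0.70). Both lists hold only miRNAs numbered below 1000. Whether they rose more than other such miRNAs was not tested.

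Of the myeloid miRNAs, 11 of 12 tested passed as higher and 1 as lower (11 and 1 adjusted over the list alone). miR-142a-3p, a blood-cell miRNA, was at 0.68 (SE 0.13, adjusted p = 0.0024), but at −0.31 with normexp, and its call ended with quantile normalization (0.28) and within row 1 (0.43); miR-15b-5p rose by 1.58 and miR-16-5p by 1.33. The member called lower, miR-342-5p, was detected in LPS only with no bound above 1, so its direction is not readable, and of the 3 myeloid members detected in LPS only miR-142a-5p alone had a bound above 1, at least 1.20-fold, which fell below 1 with median centring. As a list the myeloid miRNAs did not stand apart from the other tested miRNAs (camera adjusted p = 0.122), though the list passed without LPS replicate 1, without LPS replicate 3, with normexp, with the highest floor, with well above background as detection, over miRNAs detected on all 6 arrays and with no filter. The p53 and hypoxia list had 7 of 7 tested members higher (7 adjusted over the list alone), including miR-34c-5p, well above background on no control array and at least 2.11-fold higher (its call ended with normexp, at 0.029, and it reversed with the gene total), at a camera adjusted p of 0.0784. It too passed without either of these replicates, with either raised floor, with well above background as detection, over miRNAs detected on at least 1 array and with no filter; it also passed within row 1, where a single LPS array leaves the spread to the controls. In the miR-232724 group 6 of 7 passed as higher (6 adjusted over the list alone), led by miR-23b-3p at 1.71 and miR-23a-3p at 1.67 (camera adjusted p = 0.168; the list passed with normexp and with no filter). In the miR-29 and miR-30 families 9 of 11 were higher and 1 lower (9 and 1 adjusted over the list alone), with miR-29a-3p at 1.66, miR-30d-5p at 1.70 and miR-30c-2-3p at −3.36 (camera adjusted p = 0.263). In the miR-15/16 family 5 of 7 were higher (5 adjusted over the list alone; camera adjusted p = 0.295). Members detected in LPS only numbered 2 in the p53 and hypoxia list, 2 in the miR-232724 group, 4 in the miR-15/16 family and 4 in the miR-29 and miR-30 families; among these 2 had a bound above 1, miR-30b-5p at least 2.01-fold and miR-30c-5p at least 1.02-fold, the latter below 1 with median centring. With no filter the miR-29 and miR-30, miR-15/16 and epithelial lists passed too. In fry over the members detected on all 6 arrays, which does not compare a list with other miRNAs, 9 lists with 3 or more such members tested up on balance (largest adjusted p = 2.76e-06) and the miRNAs numbered 1000 or above tested down (adjusted p = 3.33e-06). Over all tested members the latter also tested down (adjusted p = 0.00322), although their mean was 0.00 and their median 0.29.

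Among markers of other sources, miR-183-5p and miR-128-3p were higher in LPS. Of 8 serum and erythroid markers on the array only miR-192-5p was tested, detected in LPS only with no bound above 1. Of 15 mesenchymal and muscle markers 2 were tested, miR-10a-5p at 1.01 (SE 0.04), whose call ended with the gene total (0.69), and miR-10b-5p, detected in LPS only with no bound above 1. Of 11 epithelial markers 4 were tested and 4 passed as higher (4 adjusted over the list alone), the miR-183 cluster members miR-183-5p at 2.20, miR-96-5p, well above background on no control array and at least 1.16-fold (below 1 with median centring; its call ended with quantile normalization and it was at −0.56 with normexp), and miR-182-5p, detected in LPS only at least 1.76-fold, together with miR-200c-3p, detected in LPS only with no bound above 1 (camera adjusted p = 0.168). The lymphocyte list had 3 tested members, all detected in LPS only with no bound above 1 (camera adjusted p = 0.491). The neural list had 4 tested, with miR-128-3p at 2.07 (SE 0.06), with miR-219a-5p detected on 2 of 3 control arrays, well above background on none and at least 1.47-fold higher, and with miR-138-5p and miR-338-3p detected in LPS only with no bound above 1 (camera adjusted p = 0.665). miR-219a-5p was at −0.30 with normexp and −0.077 with the gene total, where miR-128-3p was at −0.79. With normexp background correction the medians of the epithelial, lymphocyte, neural and miR-15/16 lists were below 0, at −0.13, −0.65, −0.47 and −0.59.

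miRNAs numbered 1000 or above split in both directions. Of 192 tested, 100 passed as higher and 74 as lower (100 and 74 adjusted over the list alone), and 83 of the 192 were detected in LPS only, 12 of them with a bound above 1. The list differed from the other tested miRNAs by −0.94 in camera (adjusted p = 9.5e-05; adjusted p = 0.478 with an estimated correlation), by −0.87 with the slide row as a block and by −0.71 within row 1; the call ended with no filter. Its median change was 0.29 and its mean 0.00, so the test points down while the median is above 0; among the 94 detected on all 6 arrays the median was −0.71. With spike-in scaling 162 were higher and 26 lower. Of the 5 brightest miRNAs, miR-6931-5p rose by 3.03 (SE 0.05, 8.20-fold) and miR-21a-5p by 1.36, miR-8110 fell by 2.27 (SE 0.05), miR-1224-5p fell by 0.42 (SE 0.06), and miR-6769b-5p was at 0.10 (SE 0.06, adjusted p = 0.136). With spike-in scaling miR-8110 was at 0.14 and miR-1224-5p at 1.99; without scaling they were at −0.043, which ended the call, and 1.80. miR-6769b-5p passed as higher without scaling (2.32) and with spike-in scaling (2.51), and was at −0.36 with quantile normalization. The probes of miR-8110 and miR-1224-5p are 11 bases long, with 90.9% and 72.7% GC. Whether probes this short bind only the named miRNA was not tested.

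Besides miR-6946-5p and miR-300-5p, the lowest log2 changes were those of miR-883a-5p at −3.90 (SE 0.04), miR-3059-3p at −3.84 (SE 0.04), miR-1966-5p at −3.80 (SE 0.04), miR-7075-5p at −3.64 (SE 0.06) and miR-6418-5p at −3.58 (SE 0.05). miR-6961-5p and miR-7084-5p were at −3.38 and miR-30c-2-3p at −3.36, each in 3 of 3 LPS samples below every control, and miR-8108, well above background on no LPS array, was at least 9.54-fold higher in control. With spike-in scaling these stayed lower, for example miR-6946-5p at −1.81 and miR-30c-2-3p at −0.95. The probes of miR-883a-5p, miR-3059-3p, miR-1966-5p, miR-6418-5p, miR-7084-5p and miR-30c-2-3p contain TCTC, and those of miR-7075-5p, miR-6961-5p and miR-8108 do not. Whether the TCTC probes bind only the named miRNA was not tested.

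A total of 187 miRNAs were detected in LPS on 3 of 3 arrays and in control on none. Only 34 of them had a bound above 1 (24 with median centring) and 10 reached 2-fold. The largest were miR-202-3p at least 4.90-fold, miR-350-3p at least 4.53-fold, miR-706 at least 4.11-fold, miR-6907-5p at least 3.48-fold and miR-6360 at least 2.53-fold. In the opposite direction 3 miRNAs were detected in control only. Their log2 bounds were 2.72 for miR-703, 2.31 for miR-9769-5p and 2.10 for miR-7022-5p, which are 6.61-fold, 4.96-fold and 4.29-fold. On the control arrays the lowest unscaled signal well above background was 33.7 to 34.4. The control mean of miR-7022-5p, 29.8, lay below this, so its bound is not readable, and that of miR-9769-5p, 34.4, lay at this limit. Without LPS replicate 1 the log2 bounds of miR-703, miR-9769-5p and miR-7022-5p were 1.25, 0.84 and 0.63, with 6 miRNAs detected in control only. Without LPS replicate 3 they were 1.42, 1.005 and 0.79, and with spike-in scaling they were 0.31, −0.10 and −0.31. Leaving out either replicate lowered the 3 bounds by equal amounts. This points to the floor, which was set anew from the arrays kept, and not to the signals of these miRNAs.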

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

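The test of hybridisation, scanning or feature extraction was chosen only after the result was seen. So were the tests of labelling, slide row, small-RNA share, scaling, the LPS-induced list and the splits of the samples. Of the control features outside the miRNA measurement, 5 were brighter in LPS before scaling: hur_1 by 10.1-fold, hur_2 by 38.2-fold, hur_4 by 22.4-fold, hur_6 by 10.3-fold and mr_1 by 30.02-fold, each with every LPS array above every control array. The bright corner feature went the other way, with an LPS over control ratio of 0.711, and the negative controls were at 0.715 to 0.926. What these features target is not given in the sources used here.

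The LPS arrays were brighter over the shared miRNAs by 4.67-fold. Hybridisation, scanning or feature extraction is argued against, since the spiked-in RNAs were not brighter, with a ratio of 0.880 (SD 0.0880). Labelling stays open: the highest single spike-in log2 difference was 0.0098, but which of them were added before labelling is not given in the sources used here. A row effect is argued against by LPS 1, which lay 4.24-fold above the mean of the controls of its own row. A larger share of small RNA in the LPS exosome RNA, or more exosomal miRNA per unit of RNA after LPS, may account for the 4.67-fold difference and cannot be told apart here, because no table holds the RNA makeup.

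Of 110 miRNAs called lower, 38 were also lower with spike-in scaling. Scaling to the shared miRNAs is argued against as the cause of every lower call, since 39 of the 110 were still called lower without scaling, 37 of them among the 77 well above background on at least 1 control array. Another 62 were then called higher, which the brightness of the LPS arrays gives whatever its source, so whether scaling accounts for some of the calls stays open. A linear trend on GC content and probe length held little of the spike-in scaled change of miRNAs detected on all arrays (R² = 0.054). For the 32 of the 38 detected on all arrays, the median was −0.66 before and −0.66 after this trend was removed. The lower quartile of the others was 2.22. The 32 were picked by this same change, which so weak a trend could hardly move, so the comparison does not decide about probe make-up. A higher C and T content of the probe went with lower changes among 166 other miRNAs (Spearman's rho = −0.36 across miRNAs, p = 2e-05), an idea taken from the 38 probe sequences, but rho was −0.07 among the 93 numbered below 1000 and −0.35 among the 73 others, and an effect of LPS on these miRNAs stays open.

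The 9 members of the LPS-induced list detected on all 6 arrays had a mean change of 2.05. Random level-matched lists of 9 miRNAs numbered below 1000 and detected on all 6 arrays reached it in a share of 6e-04 (median 1.08), which argues against a general rise of older-numbered miRNAs as the whole cause. Such lists drawn from all miRNAs detected on all 6 arrays reached it in a share of 1e-04 (median 0.15), the smallest 10000 draws can give, which argues against signal level. RNA makeup, labelling and an effect of LPS stay open and untested, and the 10 members of the list reported to fall were called higher too.

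For the counts of changed miRNAs, 1 of 10 splits gave as many as the real 380, with 0 as the highest other, and 1 of 10 gave as many as the real 252 with at least 2-fold change, with 0 as the highest other. For lists past camera, 7 of 10 splits gave at least the real 5, with 7 as the highest other; each other split still parts the groups 2 to 1, so this is no value for unchanged lists. A set of 10 splits is too few for a share under 0.05.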

How the results depend on the processing

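Spike-in scaling, the highest floor, the comparison within slide row 1 and the signal ratio alternatives were chosen only after the result was seen. Over 27 settings, 51 named miRNAs gave 1375 comparisons, of which 1339 kept direction and side of the threshold, 7 became weaker, 8 stronger and 21 reversed; leaving out 1 replicate kept 305 of 306. For lists, 281 of 346 kept both, 35 became weaker, 20 stronger and 10 reversed. Signal over background limits the dim miRNAs, and causes not named were not tested.

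Lower counts were 59 (44 with 2-fold) with the percentile over all miRNAs, 39 (15) without scaling, and 38 (10) with spike-ins, and 2-fold higher counts were 302 and 303; among miRNAs on every array 33 and 32 were lower. Normexp gave 113 higher (53 with 2-fold) and 284 lower; its offset of 50 is added before scaling, which raises dim control values once these are scaled. Fewer miRNAs tested gave 115 higher (81) on all 6 arrays; well above background as detection gave 170 (93) and 5 in control only; no filter gave 269 lower (194). The highest floor gave 169 higher (103), and slide row 1 gave 114 2-fold higher. Lists called higher were 0 with the all-miRNA percentile, no scaling, quantile, gene total signal, the value table and spike-ins, 1 with either block, and 10 with no filter, which called 0 lower. The signal ratio was 5.82 by the median, 2.04 over all miRNAs and 5.32 over spike-ins.

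Leaving out 1 replicate gave 187 to 269 higher and 85 to 119 lower, and 116 to 183 and 57 to 74 with 2-fold. On every array 113 to 116 were higher and 76 to 84 lower. It gave 3 to 6 lists higher, and 3 to 6 miRNAs in control only. The floor was set anew from the arrays kept each time, so the counts over all tested miRNAs do not vary with the replicates alone. With the replicate block 270 and 110 miRNAs were called, 269 and 110 of them the same, and 1 list was called higher in place of 4. Deviations from the group mean had r of −0.16, −0.06 and −0.05 between same-numbered samples, and −0.19 to 0.21 between others. This gave no sign of pairing, but 3 arrays per group cannot show that the samples were not paired.

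Reversed: miR-1224-5p was at 0.77 with the all-miRNA percentile, 1.80 without scaling, 0.24 with the probe mean and 1.99 with spike-ins, and miR-8110 at 0.14 with spike-ins. miR-6769b-5p was at −0.36 with quantile, −0.22 median-centred, −0.54 in the value table and −0.10 with well above background. Normexp put miR-142a-3p at −0.31, miR-219a-5p at −0.30 and miR-96-5p at −0.56. The gene total put miR-1224-5p at 0.094, miR-128-3p at −0.79, miR-146b-5p at −1.79, miR-155-5p at −1.04 (on control 1 its total was 37.4 times its probe sum), miR-219a-5p at −0.077, miR-29b-3p at −1.42, miR-300-5p at 0.14, miR-34c-5p at −1.68 and miR-96-5p at −1.76. Log2 bounds were −0.12 unscaled and −0.31 with spike-ins for miR-7022-5p, −0.10 with spike-ins for miR-9769-5p and −0.049 median-centred for miR-142a-5p. The lymphocyte list was at −0.64 unscaled, −0.26 with normexp, −0.75 with spike-ins, −0.20 with the highest floor, −0.23 in row 1, and from −0.23 to 0.70 leaving out 1 replicate, with −0.22 and −0.23 without LPS replicates 1 and 3. The neural list was at −0.20 with the gene total and −0.10 with a floor of 1, which put the miR-29 and miR-30 families at −0.063.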

Other observations

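The CA-repeat and TCTC tests were chosen only after the result was seen, from probe sequences of the miRNAs lower with either scaling. Several of these miRNAs share simple repeats: miR-466i-5p, miR-574-5p, miR-1187, miR-3082-5p, miR-669n and miR-32-3p have CA-repeat probes, and the changes of miR-466i-5p and miR-574-5p were −2.70 and −2.78 (−0.29 and −0.37 with spike-in scaling). They were named after their values were seen.

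Among the 32 lower with either scaling and detected on all arrays, 6 had a probe with CACACA, against 1 of 166 others (Fisher's exact test, p = 7.23e-05), and 21 had TCTC against 29 of 166 (Fisher's exact test, odds ratio 8.88, p = 1.15e-07); 27 of 32 had one or the other. Both are hypotheses found on the same data; repeat-like probes may bind RNA other than the named miRNA, which these p-values do not decide.

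miRNAs of one genomic cluster were not shown to change more alike than shuffled ones: over 18 neighbouring pairs within 10 kb the mean difference was 1.41, against 1.74 when shuffled (share of shufflings as small 0.2). This mean leans on few pairs. Differences of 7.26, 3.66, 3.55 and 3.35 each involved miR-300-5p, miR-30c-1-3p or let-7d-3p, at −4.12, −2.86 and −1.61. The other pairs differed by 0.076 to 1.49, so the test does not show that clusters move apart. The arms of one hairpin differed by 1.98 over 4 pairs, against 2.15 when shuffled (share 0.42), and with 4 pairs this says little. miR-30c-2-3p fell, while miR-30c-5p was detected in LPS only, at least 1.02-fold (below 1 with median centring).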
